A study of Danio rerio with 2 samples.

How the data were processed

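Messenger RNA of whole zebrafish embryos of the Tuebingen strain was profiled by short-read sequencing at 4.7 h after fertilization, per the labels. A morpholino is a synthetic antisense oligomer that blocks the translation or splicing of a chosen transcript. Embryos had received 5 ng of either a standard (control) morpholino or a phf14 morpholino at the 1-cell stage. Each condition is represented by 1 library, so no estimate of spread between embryos, clutches or libraries can be made and no p-value is given. How many embryos were pooled per library is not given in the sources used here. Per the labels' protocols, libraries were made from 1 ug of total RNA with an Illumina TruSeq RNA kit.

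The authors deposited 1 table per library with an Ensembl gene identifier, a gene symbol and 1 expression signal per gene; per the file headers the column is titled only as expression. The values are not whole numbers, have at most 2 decimals and are never negative. They were therefore treated as a normalised expression signal of unstated scale, comparable between the libraries as far as the authors' own normalisation allows. The aligner, the genome build, the annotation, the quantification tool and the scaling are not given in the sources used here. The sequencing depth is unknown, so no counting interval is given. A value of 0 is reported only as listed at 0.

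Both tables list the same 4591 genes in the same order, which is a part of the annotated genes; why these genes are listed is not stated, and phf14 itself was not analysed here. Of these genes 3972 carry an Ensembl identifier and 619 do not, and 3910 of the identifiers were found in the gene name table used as a reference. Gene names are those of the deposited tables. A further 4 symbols had been turned into calendar dates and 2 into bare numbers, and these were not named. In addition, 3 symbols and 3 identifiers each occurred on 2 lines and were kept as separate genes. No genome sequence or coordinates were used.

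For each gene the log2 ratio of the phf14 morpholino over the standard morpholino library was computed as the log2 of (value + 1) in the former minus that in the latter, which understates the change of genes with low values. The 3524 genes with a mean of at least 1 over the 2 libraries entered all summaries. Genes past a 2-fold difference were counted as a description of these libraries. For gene lists with at least 3 measured members, the median log2 ratio was set against the medians of 10000 random lists of the same size drawn from the same bins of mean log2 value (10 bins of equal size), and the percentile among them is given. A list is described as standing apart where its median lay outside the central 95% of random medians. This describes the 2 libraries and is not a test of the treatment.

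The 20 gene lists, covering 365 genes of which 138 are listed in the tables, were fixed before the data were examined, as were the gene naming rule and the first set of alternative settings. They cover genes activated in the zygote, oocyte (maternal) transcripts, maternal activators of the zygotic genome, Nodal and mesendoderm genes, BMP and ventral genes, dorsal organizer genes, FGF synexpression genes, Wnt pathway genes, neural ectoderm, the enveloping layer, the yolk syncytial layer, germ plasm, the p53 response, the cell cycle, ribosomal proteins, mitochondrially encoded genes, housekeeping genes, markers of later tissues, relatives of PHF14 with the same kind of domain, and reported PHF14 partners. The lists share members: 5 of the 15 measured zygotic activation genes are also in the mesendoderm list and 6 in the ventral list. Of the 6 measured germ plasm genes, 2 are also in the oocyte list. The genes named are the 8 highest and the 8 lowest log2 ratios among genes with a mean of at least 5 and a standard symbol, and up to 2 members at each end of each list.

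Alternatives comprised pseudocounts of 0.1 and 5, centring on the median gene, an unweighted trimmed mean of M values factor (30% of ratios and 5% of levels trimmed at each end) computed directly because the values are not counts, no filter or a mean of at least 5, thresholds of 1.5-fold and 4-fold, list means in place of medians, and random lists not matched on level. Chosen after seeing the data were a mean of at least 10, matching in 30 level bins and 6 further gene lists. On simulated data built on the standard morpholino library, 97% of 200 genes changed by 1.5 log2 units were recovered past 2-fold among 3460 genes, with 0 unchanged genes past it at a simulated SD of 0.2. The changed genes were drawn only from those with a value of at least 10 in the standard morpholino library. The recovered share therefore does not cover genes with lower values. Of 1000 unchanged 15-gene lists, 4.9% fell outside the central 95%, and 100% of 100 lists lowered by 0.3 log2 units fell under the 2.5th percentile. That SD is below the 0.35 seen between the libraries. The simulation was repeated at 0.35, a value chosen after seeing the data, which includes any true differences. In the repeat the change and the variation were added on the scale of log2 of (value + 1), not to the value itself. It recovered 95% of the same changed genes among 3489, and put 7 unchanged genes past 2-fold higher and 4 lower of 3289. It left 3.5% of unchanged lists outside the central 95% and found 73% of lowered lists under the 2.5th percentile. In both simulations unchanged genes varied independently around 0 without a trend with level, and the lists were drawn from them at random. The shares of lists outside therefore check the computation and not lists whose members vary together. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.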

Results

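Expression was compared between whole zebrafish embryos injected with a phf14 morpholino and embryos injected with a standard morpholino, both collected at 4.7 h after fertilization, in the late blastula period when the embryo's own genome has recently become active. PHF14 is a chromatin protein that binds histone H3, and the series addresses its part in zygotic genome activation. The data comprise 1 library per condition, so every difference below is between these 2 libraries and has no replicate error. The deposited values of the 4591 listed genes summed to 75675 in the standard morpholino library and 71136 in the phf14 morpholino library, with medians of 2.77 and 3.10. Sequencing depth is unknown. The 10 most abundant genes held 28.3% and 26.6% of these totals, and 26 and 25 genes respectively were listed at 0, of which 10 were at 0 in both. The targeted transcript, phf14, was not analysed here, so the tables give no check of the knockdown.

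The first question was how far the listed genes as a set differed between the 2 libraries. With a pseudocount of 1, 99.2% of the 3524 genes with a mean of at least 1 lay within 2-fold between the libraries. Across these genes the log2 values correlated with a Pearson r of 0.976 (genes are not independent replicates). The log2 ratio of the phf14 morpholino over the standard morpholino library had a median of 0.11 and an SD of 0.35 across genes. With the values as deposited, 2197 genes were higher and 1312 lower in the phf14 morpholino library. The median shift of 0.11 depends on the scaling between libraries, and centring on the median gene subtracts 0.11 from every log2 ratio and list median below, which can be much of a small value. The ratio also depended on level. When the genes were ranked by level and cut into 10 equal bins, the most abundant bin (353 genes) had a median of -0.15, with 72.8% of genes lower in the phf14 morpholino library, whereas the medians of the other bins lay between 0.07 and 0.18.

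Genes past 2-fold numbered 12 higher and 17 lower in the phf14 morpholino library, of which 6 and 11 had standard symbols. Simulated unchanged genes with the observed SD of 0.35, which includes any true differences, gave 7 higher and 4 lower among 3289. Part of the observed counts can therefore come from the spread alone. The simulation was centred on 0 without a trend with level, unlike the observed ratios with their median of 0.11. It therefore does not give the number to expect on each side. The counts depended on the pseudocount: with 0.1 they were 51 and 32, and with 5 they were 2 and 3. They also depended on the scaling, with 8 higher and 24 lower after centring on the median gene. The gene with the greatest excess among those named by rule was sowahd (ENSDARG00000087152), which encodes an ankyrin repeat protein, at 1.56 in the standard and 17.79 in the phf14 morpholino library (log2 ratio 2.88). Next came mtmr14 (ENSDARG00000059642), a phosphoinositide phosphatase, at 2.35 and 7.78 (1.39). rtkn2a, a rhotekin family gene, was at 19.69 and 43.77 (1.11), and pcm1, which encodes a centriolar satellite protein, at 8.73 and 19.97 (1.11). zdhhc20b, a palmitoyltransferase gene, had a log2 ratio of 1.02. pcgf6, a Polycomb group RING finger gene, had 0.96, the actin nucleation promoter gene wasla 0.94 and the lysosomal cation channel gene tpcn2 0.93.

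At the other end stood gtf2a1 (ENSDARG00000011000), which encodes a subunit of the general transcription factor TFIIA, at 269.67 in the standard and 110.21 in the phf14 morpholino library (log2 ratio -1.28). The mitochondrial fatty acid oxidation gene hadhaa was at 7.79 and 2.62 (-1.28). her7 and her1, hairy-related repressors that oscillate during somite formation, were at 13.17 and 5.05 (-1.23) and at 8.59 and 4.01 (-0.94). The epithelial genes evpla (envoplakin) and esrp2 (a splicing regulator of epithelial cells) had log2 ratios of -1.15 and -1.14. apoc2, a cofactor of lipoprotein lipase, had -1.07. rpl26 (ENSDARG00000102317), a ribosomal protein gene, was at 277.49 and 131.85 (-1.07). The SD of log2 ratios among genes of similar level was between 0.31 and 0.37, and it includes true differences between genes as well as measurement error.

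**Figure D1:**
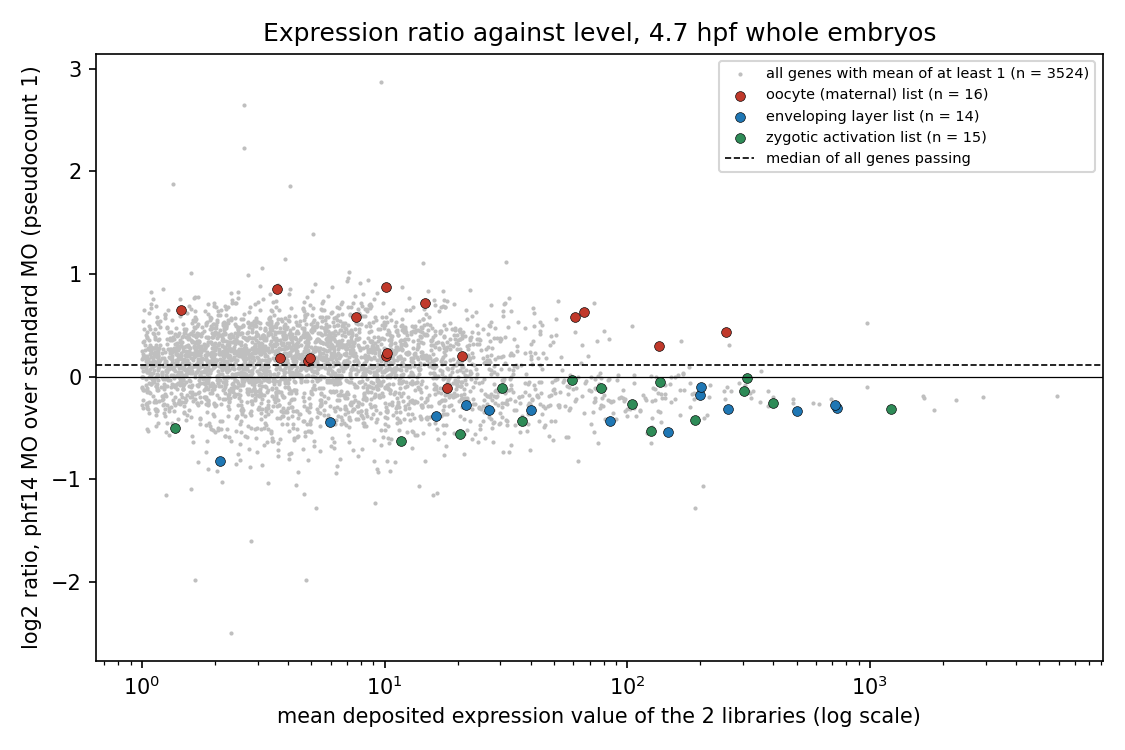
Log2 ratio of the phf14 morpholino over the standard morpholino library (vertical axis, pseudocount 1) against the mean deposited expression value of the 2 libraries (horizontal log axis); each point is a gene, grey for all 3524 genes with a mean of at least 1 and coloured for the oocyte (16), enveloping layer (14) and zygotic activation (15) lists. The dashed line is the median gene at 0.11; all but 1 of the oocyte genes lie above it, and all enveloping layer and zygotic activation genes lie below 0.

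The second comparison asked whether transcripts made by the zygote and transcripts supplied by the oocyte differed between the libraries. All 15 measured zygotic activation genes had lower values in the phf14 morpholino library, against 10 in the median random list of the same levels. Their median log2 ratio was -0.26, a ratio of 0.833, or -0.37 relative to the median gene. The lowest were eve1, a ventral and posterior homeobox gene, at 14.35 and 8.93 (-0.63), and sp5l, a Wnt-responsive transcription factor gene, at 24.61 and 16.43 (-0.56). The early ventral repressors vent and vox were nearly level between the libraries, at 59.96 and 58.46 (-0.04) and at 313.15 and 310.22 (-0.01). Random lists matched on level had a typical median of -0.12, so the zygotic list lay at -0.14 relative to genes of like level. Their median was below that of the zygotic list in 1.42% of draws. The list no longer stood apart when only genes with a mean of at least 5 were kept (3.02%, 14 genes), although its median was then again -0.26.

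Oocyte transcripts went the other way. Of the 16 measured, 15 had higher values in the phf14 morpholino library, with or without centring on the median gene, against 9 in the median random list. The median log2 ratio was 0.37, a ratio of 1.29, or 0.26 relative to the median gene, and 99.92% of random medians lay below it. btg4, which encodes an adaptor for the deadenylation of maternal mRNA, was at 6.89 and 13.45 (0.87). bmp15, an oocyte growth factor gene, was at 2.28 and 4.92 (0.85). The germ plasm organizer gene buc was at 10.90 and 18.52 (0.71). The smallest excess was that of mos, the oocyte maturation kinase gene, at 4.55 and 5.15 (0.15), and org was the single member with a lower value, at 18.82 and 17.40 (-0.11). The zygotic minus the maternal median was -0.63. Random pairs of lists matched on level gave a median difference of -0.17, with a central 95% from -0.42 to 0.12, and 0.02% of pairs lay below the observed value. Of the maternal activators of the zygotic genome, sox19b (log2 ratio 0.14) and ep300b (0.10) were measured. Both lay close to the median gene, and ep300b was below it.

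The third comparison took up cell lineages and signalling pathways of the blastula. The enveloping layer, the outer epithelium of the embryo, stood apart: all 14 measured genes had lower values in the phf14 morpholino library, against 8 in the median random list, with a median of -0.33 (ratio 0.797). Level-matched random lists had a typical median of -0.09, and random medians were lower than that of the enveloping layer in 0.07% of draws. The secreted protein gene agr1 was at 2.96 and 1.24 (-0.82) and the annexin gene anxa1a at 174.13 and 119.28 (-0.54). The keratin gene krt92 (-0.18) and the claudin gene cldne (-0.10) differed least. In the Nodal and mesendoderm list 15 of 16 genes were lower (10 in the median random list), with a median of -0.26 at the 1.23rd percentile. mespab, a paraxial mesoderm transcription factor gene, was at 6.08 and 2.71 (-0.93) and tbxta, the zebrafish Brachyury gene, at 148.76 and 102.55 (-0.53). The actin bundling gene fscn1a (-0.07) and the organizer gene gsc, at 37.72 and 42.66 (0.17), lay at the other end. The percentile was 3.07 among genes with a mean of at least 5.

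The neural ectoderm list had 5 measured genes and a median of -0.32 (1.88th percentile). sox3 was at 218.67 and 162.49 (-0.43) and zic2a at 11.46 and 8.86 (-0.34). The anterior gene otx1 was the exception at 11.43 and 17.35 (0.56), and the mean of the list lay at the 11.29th percentile. The neural ectoderm list also no longer stood apart with a mean of at least 5 (9), a pseudocount of 5 (7.65) or the trimmed mean factor (2.86). Yolk syncytial layer genes were all lower (5 of 5, against 3 in the median random list), with a median of -0.31 at the 5.17th percentile. hnf4a, an endodermal nuclear receptor gene, was at 68.66 and 45.33 (-0.59) and apoc1 at 125.40 and 99.56 (-0.33). These last genes did not stand apart from random lists of such abundant genes. Germ plasm genes had a median of 0.19, or 0.08 relative to the median gene (71.28th percentile, 6 of 6 higher against 4 in the median random list). They ranged from tdrd6 (0.02, below 0 after centring) to buc, with tdrd7a at 0.46. Of these 6 genes, 2, including buc, are also in the oocyte list, so their direction is not independent of the oocyte result.

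Signalling lists lay within the range of random lists. BMP and ventral genes had a median of -0.09, or -0.20 relative to the median gene (12 genes, 27.51st percentile). They ranged from eve1 (-0.63) and cdx4 (-0.50) to id2a (0.06) and szl (0.07), the last 2 falling below 0 after centring. The values of cdx4 were low, at 1.78 and 0.97, and its log2 ratio ran from -0.81 to -0.18 across the alternatives. Dorsal organizer genes had -0.19, or -0.30 relative to the median gene (8 genes, 6.87th percentile), with hhex at -0.42 and gsc at 0.17. FGF synexpression genes had -0.15, or -0.26 relative to it (10 genes, 14.16th percentile), from the phosphatase gene dusp4 (-0.53) and fgf24 (-0.47) to etv5a (0.32). Wnt pathway genes had -0.24 (6 genes, 3.97th percentile), from sp5l (-0.56) to lef1 (0.18).

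**Figure D2:**
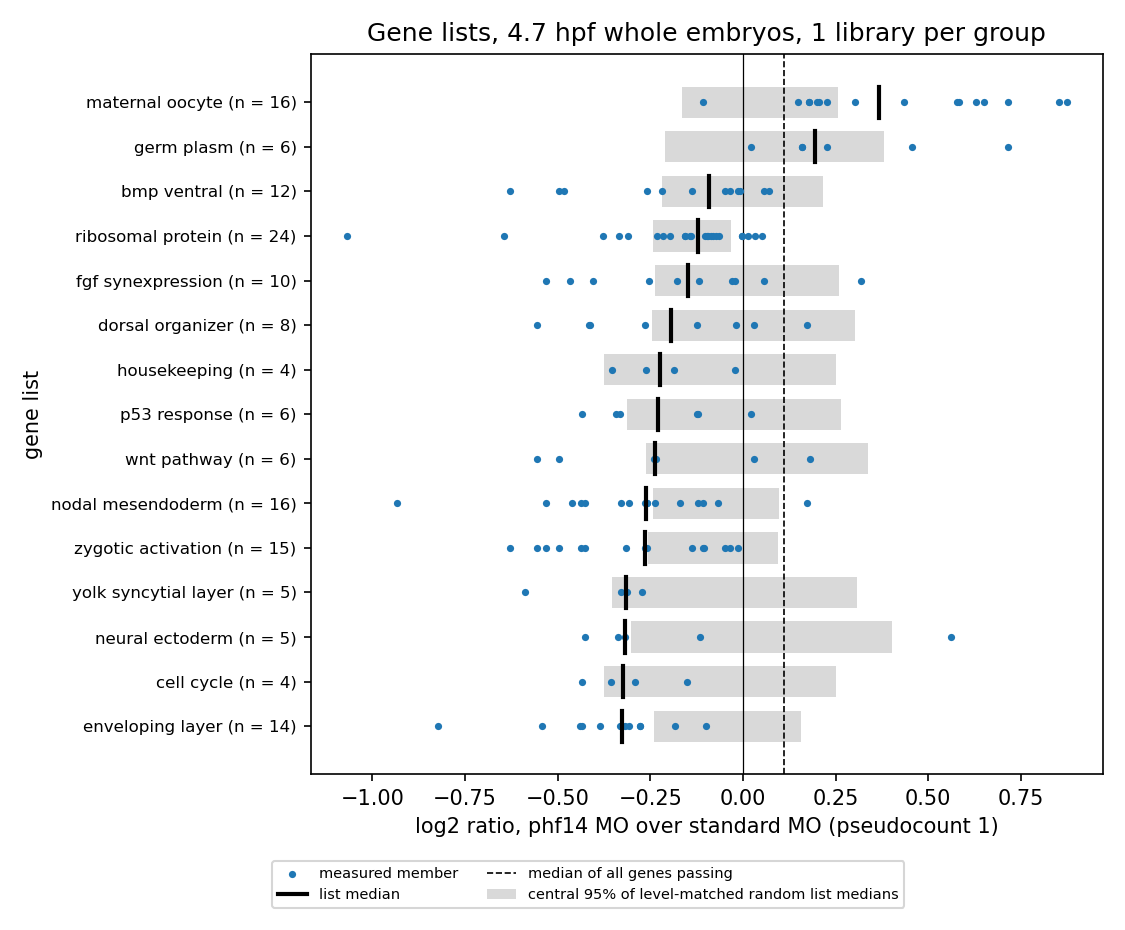
Log2 ratios of the phf14 morpholino over the standard morpholino library (horizontal axis, pseudocount 1) for the 15 gene lists with at least 3 measured members (vertical axis); blue points are genes, black bars list medians and grey bands the central 95% of medians of level-matched random lists. The oocyte list lies above its band at 0.37, and the enveloping layer (-0.33), neural ectoderm (-0.32), zygotic activation (-0.26) and mesendoderm (-0.26) lists lie below theirs.

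The remaining lists covered constitutive and stress genes. Ribosomal protein genes had a median of -0.12, or -0.23 relative to the median gene (24 genes, 74.42nd percentile). Apart from rpl26 the lowest was rpl39, at 153.38 and 97.72 (-0.65), and rps13 was at 350.64 and 363.15 (0.05, below 0 after centring). The housekeeping median was -0.22 (4 genes, 24.39th percentile), with the elongation factor gene eef1a1l1, the most abundant listed gene, at 6276.89 and 5520.76 (-0.19) and tbp at -0.35. The 4 measured cell cycle genes were all lower (3 in the median random list), with a median of -0.32 (6.04th percentile), from the replication licensing gene mcm6 (-0.44) to top2a (-0.15). Genes of the p53 response, which off-target effects of morpholinos can induce, had a median of -0.23 (6 genes, 12.18th percentile), from sesn3 (-0.43) to rps27l (0.02, below 0 after centring). Of the later tissue markers lcp1 was measured (-0.30). brpf3b (0.08, below 0 after centring) was the measured relative of PHF14, and kdm1a (-0.05) the measured partner. No mitochondrially encoded gene was analysed here.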

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

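The 2-fold counts depended on the settings. Against 12 higher and 17 lower genes, a pseudocount of 0.1 gave 51 and 32, a pseudocount of 5 gave 2 and 3, a mean of at least 5 gave 5 and 7, a 1.5-fold threshold gave 175 and 100 and a 4-fold threshold 3 and 1. Centring gave 8 and 24 and the trimmed mean factor 7 and 22, so both scalings moved the balance toward lower genes. Centring moved the zygotic and maternal medians to -0.37 and 0.26, and the trimmed mean factor to -0.41 and 0.22, with signs kept. No list median changed sign under any alternative, but many moved by over 1.5 times: BMP and ventral (-0.24 to -0.05), dorsal organizer (-0.34 to -0.18), FGF (-0.29 to -0.13), Wnt (-0.38 to -0.19), neural ectoderm (-0.43 to -0.13), p53 (-0.37 to -0.12), ribosomal protein (-0.27 to -0.12), housekeeping (-0.37 to -0.21), germ plasm (0.06 to 0.34), zygotic (-0.41 to -0.25), mesendoderm (-0.41 to -0.25) and oocyte (0.22 to 0.43). The enveloping layer (-0.47 to -0.30), yolk syncytial layer (-0.47 to -0.31) and cell cycle (-0.47 to -0.31) medians moved less. The zygotic minus maternal difference, and the percentiles of the oocyte and enveloping layer lists, stayed on their side of the central 95% of random lists under every alternative run. The zygotic percentile left the lowest 2.5% with a mean of at least 5 (3.02) or 10 (3.07) with its median still at -0.26, as did the mesendoderm percentile (3.07 and 3.11). The neural ectoderm percentile rose to 9 and 9.86 with those filters, to 11.29 for the list mean, to 7.65 with a pseudocount of 5 and to 2.86 with the trimmed mean factor. Without matching on level, the cell cycle (1.26), dorsal organizer (2.07), p53 (2.02), Wnt (1.77), yolk syncytial layer (1.2) and ribosomal protein (0.45) percentiles fell below 2.5. The yolk syncytial layer also passed with the list mean (1.72) and with no filter (1.84). The ribosomal protein list moved to the upper side with 30 level bins (98.48) or a mean of at least 10 (98.23). The cause of these moves was not tested. Of 74 named genes, 10 changed sign under an alternative, all with a log2 ratio of at most 0.10 in size, and 7 moved by more than the SD of genes of their level with the sign kept: sowahd (1.80 to 3.43), mtmr14 (0.80 to 1.69), hadhaa (-1.54 to -0.75), her7 (-1.37 to -0.85), mespab (-1.14 to -0.52), agr1 (-1.19 to -0.35) and bmp15 (0.45 to 1.08). The mean of at least 10 and the 30 level bins were chosen after seeing the data. The planned values for phf14 were not run, since the gene was not analysed here. No paired analysis was possible because each group has 1 library, and no library could be left out. The depth is unknown, and with 1 library per group the spread between libraries cannot be measured.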

Other observations

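The gene lists in this part were written after the main results had been seen, and so were the test of the level trend and the values of the late genes without some members; several members had been seen already, and for lists with at least 3 others the value without them is given. Genes of the segmentation clock and presomitic mesoderm were lower in the phf14 morpholino library in 7 of 7 cases (3 in the median random list), with a median log2 ratio of -0.82 and 0% of level-matched random medians below it. The Notch ligand gene dlc was at 3.98 and 1.99 (-0.74), dld at 7.39 and 5.43 (-0.38) and hes6 at 49.74 and 36.71 (-0.43); these 3, not seen before, had a median of -0.43 (1.74th percentile). Epithelial genes were lower in 14 of 17 cases (8 in the median random list; median -0.29, 0.08th percentile), and the 9 not seen before had the same median of -0.29 (1.22nd percentile). Among them were the desmosomal genes pkp3a (13.10 and 9.33) and dspa (19.44 and 15.77). Plasma protein and lipid transport genes were lower in 7 of 7 cases (3 in the median random list; median -0.49), with afp4 at 147.72 and 104.88, but only 2 had not been seen before.

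Heat shock genes had a median of -0.41 (8 genes, 0.05th percentile), with hsp70.3 at 57.22 and 37.98 and hsp90aa1.2 at 53.26 and 37.50. The 5 not seen before were split. Of them, hsp70.3 (-0.58) and hsp90aa1.2 (-0.50) were low, whereas dnajb1a (-0.01), hsp90aa1.1 (0.09) and hspe1 (0.10) were not. The median of these 5 was -0.01 (47.22nd percentile). A list of oocyte RNA regulators lay at the median gene (0.11, 12 genes, 43.38th percentile), with ddx6 at 2.15 and 3.39 and cpeb2 at 1.80 and 1.19; without tdrd1, seen before, the 11 others gave 0.11 (43.72nd percentile). Among 29 families of genes sharing a symbol stem, 1 lay below and 4 above the central 95% of random medians, where chance puts about 1.45 outside in all. The keratins were the low family (krt, 10 genes, median -0.28), but 6 of them are in the enveloping layer list and 3 others had been seen before, so this restates the enveloping layer result. The high ones were the F-box genes (fbxo, 9 genes, 0.43), the ubiquitin-specific proteases (usp, 11 genes, 0.34) and the unspecific stems tmem (41 genes, 0.28) and fam (39 genes, 0.24).

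The opposite position of the planned oocyte and zygotic activation lists was weighed against 3 explanations. The added list of oocyte RNA regulators, at the 43.38th percentile, did not share the high position of the planned oocyte list. A trend of the ratio with level is argued against as the whole explanation. Of 10000 random list pairs matched in 30 level bins, 0 had a difference as low as -0.63, and their central 95% ran from -0.41 to 0.06. This was a finer repeat of the planned comparison in 10 level bins, whose result (0.02%) was already known. It is not independent of that result. Part of the difference does go with level, since random pairs matched in 10 level bins had a median difference of -0.17. The zygotic list lay at -0.37 relative to the median gene but at -0.14 relative to genes of like level. For the oocyte list these values were 0.26 and 0.32. For the difference between the lists, noise of low values is argued against as well. Genes with a mean of at least 10 gave -0.63 (14 zygotic and 10 maternal genes, with 0.02% of random pairs lower). With that filter the oocyte list still stood apart (99.93rd percentile), but the zygotic list on its own did not (3.07th percentile). An earlier stage of the phf14 morpholino embryos at collection stays open: a list meant for genes with main onset at gastrulation or later, none seen before, had a median of -0.31 and 0.32% of random medians were lower, as such a delay predicts, but only 6 of its 63 genes were measured. One of them, sebox, is known as an early Nodal target and does not belong there; the 5 others gave -0.25 (1.87th percentile). The low value rests on few genes, since dlc and dld are also among the segmentation clock genes above: without them the median was -0.15 (4 genes, 7.36th percentile), and without sebox as well -0.05 (3 genes, 17.78th percentile). The list is too small to decide. Weaker or slower activation of the zygotic genome after the phf14 morpholino predicts the same and was not tested apart from it, and a difference between clutches or injections stays equally open with 1 library per condition.

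The most abundant of the 10 level bins also lay lower. Zygotic activation genes such as tbxta, sox3, vent and vox are in this bin, so it shares genes with the zygotic list. That list has only 15 measured genes, whereas the bin has 353, of which 72.8% were lower in the phf14 morpholino library. The listed zygotic genes therefore cannot account for the bin's median of -0.15, and vent (-0.04) and vox (-0.01) lay above it. The median of this bin minus that of the other genes was -0.28 (bootstrap SD over genes 0.016). That SD comes from resampling genes within this pair of libraries and does not measure the spread between libraries. What produced the low position of the bin stays open.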
